A study of Mus musculus with 3 samples.

How the data were processed

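RNA from mouse Th1 cells (primary cells, strain C57BL/6NJ) was measured by RNA sequencing in 3 libraries. The labels name the assay total RNA-seq, while the library protocol they link to is named for poly(A)+ RNA. They also link a CD4 T-cell differentiation protocol; the contents of both were not used here. Groups and replicate numbers were taken from the labels. Sex was not collected and age is unknown, per the labels.

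The deposited values are whole-number fragment counts per gene, not normalized. Per the file headers they were made with featureCounts 1.4.6-p4, counting read pairs with both ends mapped over exons summed by gene identifier, with strand setting 1 (forward), on the GENCODE M13 annotation and alignments whose names contain star2. The assembly is mm10 per the labels. The headers call the run paired-end and stranded; the library kit, the aligner's version and read trimming are not given in the sources used here. Strand setting 1 counts a fragment for a gene on the strand of the first read, so with a kit that reads the other strand it would count fragments for the opposite-strand gene. The deposited files also give each gene's length in bp, another value used to compute TPM. Read alignments and strand-specific signal tracks were not used here. No column of another series was used.

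The design written before the data were examined assumed expected counts and TPM from a quantification tool. The files hold raw counts instead, so TPM and FPKM were computed here as counts per gene length, scaled to the sum of these values (TPM) or to the total count (FPKM). Alternatives based on posterior mean TPM could therefore not be run. Symbols were matched by identifier for 50376 of 50600 genes, and biotypes were taken from a later GENCODE release on the same assembly. Coordinates are those of the deposited tables. Exonic overlap with genes of the other strand was computed with bedtools 2.31.1; 8189 genes shared at least 1 position and 42411 none.

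Totals were 4742025, 50627 and 3543816 counts in replicates 1, 2 and 3. Shares of counts have exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 counts. With 1 group, edgeR's quasi-likelihood test between groups was not possible. The biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 with an intercept-only design after TMM scaling, over genes kept by filterByExpr. Each kept gene was tested against counting error by a chi-square test with 2 degrees of freedom on TMM-scaled totals, with Benjamini-Hochberg adjustment at 0.05. The filter required counts in all 3 libraries, so it favoured genes seen in the shallow replicate 2, where expected counts were small and the chi-square approximation is rough. DESeq2 1.42.0 gave alternative size factors and dispersions. On counts simulated for 7406 genes, the chi-square test recovered 100% of genes changed 2-fold and 100% of those changed 4-fold. It called 0.33% of unchanged genes. The changed genes were drawn from those with at least 100 counts in all, and the change was made in replicate 3 only. Recovery in genes with fewer counts, or of changes in replicate 2, was not simulated. A simulated coefficient of 0.20 was recovered as 0.20.

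Gene lists for 25 cell types and programmes were fixed before the data were examined, with replication-dependent histone genes as a further list by symbol. The Th1 list was set against each of the Th2, Th17, Treg and Tfh lists by a permutation test over genes with 100000 resamples of the difference in median log2(TPM + 1), two-sided, leaving out shared genes, with Benjamini-Hochberg adjustment over the 4. On simulated lists of 22 and 14 genes this test called 5.0% with no shift and 95.0% with a log2 shift of 3, over 20 simulations each. Pairs of genes were compared as log2 TPM ratios per library with an exact sign-flip test. Ratios against 0 counts are lower bounds against 3 counts, with the count of the other gene taken as exact. List deviations used log2 CPM from edgeR with a prior count of 2 and 10000 random lists drawn within 100 expression ranks of each member, for lists with at least 5 kept genes.

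Named genes were chosen by a rule fixed before the data were examined: all members of the 5 CD4 lineage lists and the sex list, up to 4 members of each other list by mean TPM, the 10 highest nuclear protein-coding genes, the 10 varying genes with a mean CPM of at least 10 and the largest SD, and cytokines and chemokines among the 10 highest of their kind. Genes outside it are said to be chosen after their values were seen, apart from genes named only as the overlap partner of another. Results for some genes of the lists are not reported here. Alternatives changed the TPM floor, pseudocount, unit, scaling, filter and list summary, and left out each replicate in turn. Settings restricted to genes without opposite-strand exons, or to replicates 1 and 3, were added after the counts were seen. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.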

Results

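Gene counts of 3 libraries of mouse T helper 1 (Th1) cells, the CD4 T cells that secrete interferon gamma, were analysed. The cells were primary cells of strain C57BL/6NJ, and the labels number the libraries as biological replicates 1, 2 and 3 of 1 group. The file headers place the cells at 48 h of a Th1 and Th2 time course. The other arms of that course were not analysed here, so levels within each library and the spread between the 3 libraries were the comparisons this design allowed. All 3 libraries carry the same donor identifier and no label says that they came from separate animals or cultures. P-values across libraries therefore measure only the spread between these samples, which may be technical. Sex-linked genes, described below, differed between replicates 1 and 3 beyond counting error (Xist at 146 and 0.847 CPM). The shared identifier therefore does not show that the libraries hold like RNA.

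Levels are given as CPM, counts scaled to library total, and as TPM, counts per gene length scaled likewise. Depth differed between libraries. Replicate 1 held 4742025 counts over 17270 genes, replicate 3 held 3543816 counts over 16786 genes, and replicate 2 held only 50627 counts over 7749 genes. A count of 0 therefore allowed a level of up to 0.633 CPM in replicate 1, 0.847 CPM in replicate 3 and 59.3 CPM in replicate 2, taking 3 counts as the limit. Intervals and limits given here cover counting error only. Means over the 3 libraries weigh replicate 2 like the others, although a few counts there set its TPM. A gene at 0 in replicate 2 was below detection at this depth and is not described as absent.

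The most abundant nuclear protein-coding genes fell into 2 kinds. Hsp90ab1, a cytosolic chaperone (3753 ± 1127 TPM; SD, n = 3), Npm1, a nucleolar protein, Eef1a1, a translation elongation factor, and the ribosomal protein genes Rps24 and Rpl4 share no exonic position with a gene of the other strand. Gm20721 (chromosome 2, 174330319 to 174346712, minus strand, mm10), at 10680 TPM the highest of the 10, has 99.0% of its exonic length under exons of Gnas on the plus strand. Phykpl, Acat3, Gm17606 and Gm17617 also overlap opposite-strand exons, of Hnrnpab, Tcp1, Acin1 and Zfp346. Phykpl alone took 51657 counts in replicate 1, 756 in replicate 2 and 60964 in replicate 3. Gnas, chosen after its values were seen, had 1493, 16 and 706 counts against 30152, 374 and 35521 for Gm20721.

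Genes that share exonic positions with an opposite-strand gene carried more of the counts than their length. These 8189 genes make up 26.2% of the exonic length. They took 52.7% of the counts of replicate 1 (exact 95% interval 52.6 to 52.7), 57.8% of replicate 2 (57.4 to 58.2) and 72.2% of replicate 3 (72.2 to 72.3). Among pairs with at least 20 counts in which a gene lay for 90% or more of its exonic length under exons of an opposite-strand host, the embedded gene had the higher count per kb in 219 of 294 pairs in replicate 1, 38 of 48 in replicate 2 and 226 of 295 in replicate 3. The median log2 ratio of embedded gene to host was 3.82 in replicate 1 (bootstrap 95% interval 3.26 to 4.42), 4.96 in replicate 2 (3.75 to 5.99) and 5.25 in replicate 3 (4.64 to 5.81).

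The same genes separated replicate 3 from replicate 1. Relative to all counts, the 5857 genes without opposite-strand exons and with at least 50 counts over both libraries had a median log2 ratio of replicate 3 to replicate 1 of -0.84 (quartiles -1.03 and -0.63). The 212 genes embedded for 90% or more had a median of 0.78 (quartiles 0.66 and 0.97), and 205 of them were above 0 against 304 of the 5857. Genes with an overlap of up to 50% went both ways (3691 genes, median -0.07, quartiles -0.78 and 0.72), and a small overlap did not rule out a rise: Phykpl, with 8.34%, had a log2 ratio of 0.66. For levels in TPM below, an overlap of 10% or more of the exonic length is given beside them, a cut made for brevity. It does not vouch for the levels of genes without overlap. If fragments were counted on the opposite strand, an explanation weighed below, those levels would rest on the minor share assigned to the wrong strand. Bhlhe40, Irf1, Eomes, Gata3, Ikzf2, Ikzf4, Bcl6, Cxcr5, Il21, Tpi1, Gapdh, Gbp2, Psmb8, Junb, mt-Nd6, mt-Nd5 and mt-Co1 have smaller overlaps, of 0.19% to 8.92%; of these, mt-Nd5 (1.69) and mt-Nd6 (0.43) had a log2 ratio above 0.

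**Figure D1:**
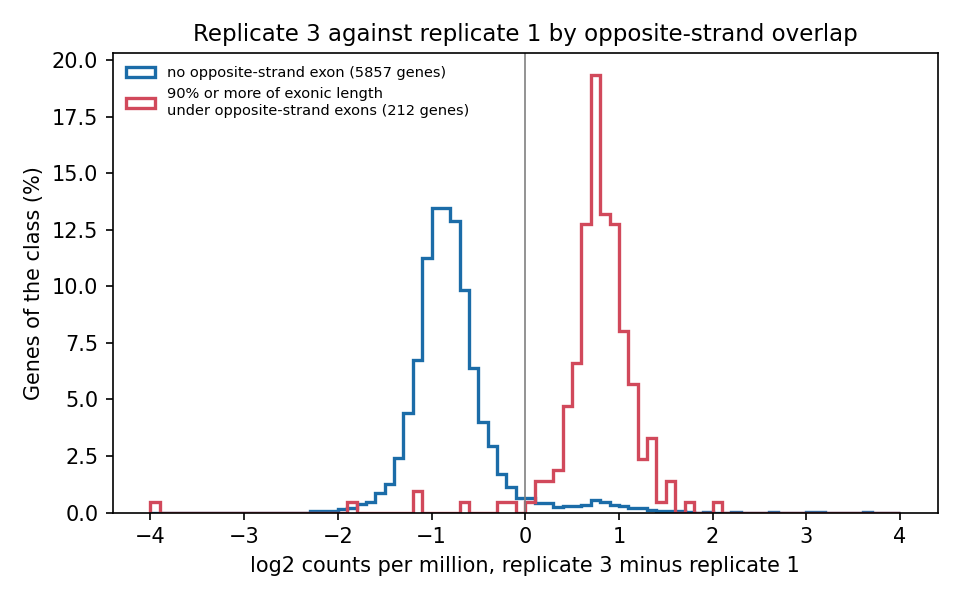
Histogram of the log2 ratio of CPM in replicate 3 to replicate 1 (x axis) as the percent of genes in each class (y axis), for genes with at least 50 counts over both libraries; values beyond 4 in either direction are drawn in the outermost bins. Genes without opposite-strand exons (5857) centre at -0.84 and genes embedded for 90% or more (212) at 0.78.

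In all, 7469 genes reached 1 TPM in every library, 6394 of them protein-coding. Replicate 2 set this number: a single count there was worth 19.8 CPM, and without replicate 2 the number was 12243. Across the 14734 genes with 1 TPM in any library, Pearson's r of log2(TPM + 1) was 0.91 between replicates 1 and 3, 0.77 between 1 and 2 and 0.74 between 2 and 3. These are correlations across genes, which are not independent replicates. The count chi-square per degree of freedom was 53.2 for replicates 1 and 3, 3.12 for 1 and 2 and 5.39 for 2 and 3. No pair agreed within sampling noise, so all 3 libraries were kept as separate samples. For a given difference this statistic grows with depth, so its lower values with replicate 2 do not show closer agreement.

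The common biological coefficient of variation between the 3 libraries was 0.341 over 7406 genes, and 4681 of them (63.2%) varied beyond counting error at an adjusted p under 0.05. Replicates 1 and 3 carried most of that call, since pairs with the shallow replicate 2 gave the test little power. It fell to 677 of 7147 genes without replicate 1 and to 271 of 7427 without replicate 3, and was 4167 of 11003 without replicate 2. The coefficient, which allows for counting error, was 0.365 without replicate 1, 0.363 without replicate 2 and 0.241 without replicate 3. The fewer calls therefore do not show that replicate 2 was like the others. In genes without opposite-strand exons, a choice made after the counts were seen, the coefficient was 0.164 and 560 of 4136 genes varied. Of the 10 varying genes with the largest SD, Gm15247 and Gm15726, both antisense to Mid1, had 21, 3 and 393 and 97, 12 and 1432 counts in replicates 1, 2 and 3. Rnf166, Gla, Trp53i11, Cd160, Gm17968 and Ngly1 owed their place to replicate 2, where they had 4 to 6 counts. Gm26613 and Spout1 had 1 count each there.

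The libraries held a T cell transcriptome. All 16 genes of the T-cell receptor complex and pan-T-cell list reached 1 TPM in every library, with a list median of 6.73 ± 0.53 (SD, n = 3) in log2(TPM + 1). Trac, the T-cell receptor alpha constant region, stood at 229 ± 114 TPM, Trbc1 at 190, 386 and 90.8 TPM in replicates 1, 2 and 3 (7 counts in replicate 2) and Cd5, a surface regulator of receptor signalling, at 326, 99.8 and 142 TPM. Thy1 stood at 178 ± 67.4 TPM.

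Of the 22 genes of the Th1 list, 12 reached 1 TPM in every library and 15 in both replicates 1 and 3. Lta, the cytokine lymphotoxin alpha, led the list at 482 ± 208 TPM (n = 3). Bhlhe40 (116 ± 43.1 TPM), the lineage regulator Tbx21 (83.2 ± 27.0 TPM; chromosome 11, 97098071 to 97115331, minus strand), Irf1 (55.7 ± 23.4 TPM) and Ifng, the gene of interferon gamma (45.0 ± 24.6 TPM; chromosome 10, 118441046 to 118445892, plus strand) stood below it. The receptor chain Il12rb1 and the transcription factor Stat4 stood at 32.1 ± 16.6 and 30.6 ± 16.2 TPM. Fasl, Runx3, Eomes, Nkg7, Il18r1 and Il18rap had mean levels between 2.07 and 24.1 TPM, with 0 to 2 counts in replicate 2. The chemokine receptors Cxcr3 and Cxcr6, the chemokine Ccl5, and Havcr2, Hlx and Twist1 had at most 6 counts in any library. Il12rb2 (16.2 ± 5.26 TPM) has 40.0% of its exonic length under exons of Serbp1.

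Genes of other CD4 lineages were set against the Th1 list in the same libraries. The median of the Th1 list exceeded that of the Th17 list by 3.12 in log2(TPM + 1) and that of the Th2 list by 2.40, each in 3 of 3 libraries. Neither passed Benjamini-Hochberg adjustment over the 4 lists (permutation over genes, two-sided: p = 0.048, adjusted 0.19 for Th17; p = 0.10, adjusted 0.21 for Th2). In replicate 2 the Th17 and Th2 medians were both 0, on 3 and 6 counts. Its difference of 3.33 for each was therefore the Th1 median alone. The Th17 difference was 3.32 without replicate 2 (adjusted permutation p = 0.030) and 1.94 in members without opposite-strand exons (adjusted permutation p = 0.74), where the Th2 difference was 1.37; in those members with replicates 1 and 3 alone they were 2.90 and 2.36. The Th1 median was 1.37 above that of the Tfh list (adjusted permutation p = 0.64) and 0.56 below that of the Treg list (adjusted permutation p = 0.93), or 0.76, 0.10 and 0.38 below it without replicate 1, 2 and 3. In members without opposite-strand exons the Treg difference was -1.80 and the Tfh difference turned to -1.18; with replicates 1 and 3 alone these were -0.61 and -0.14. Genes are not replicates, and these tests compare lists within these libraries.

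Members of the other lineage lists differed widely. In the Th2 list, 2 of 14 genes reached 1 TPM in every library and 6 in both replicates 1 and 3. Gata3, the Th2 regulator, had 68, 0 and 37 counts, Il13 had 34, 0 and 17, Il5 had 3, 0 and 0, and Il9, Ccr3 and Il24 had none. The chemokine receptor Ccr4 stood at 29.1 ± 14.3 TPM, and Ptgdr2, at 36.7, 0 and 55.3 TPM in replicates 1, 2 and 3, has 39.0% of its exonic length under exons of Ccdc86. In the Th17 list, Ccr6 stood at 30.6 ± 13.2 TPM, whereas Il17a, Il22, Ccl20 and Tmem176b had no count and Il17f had 3. The Treg list was led by genes that activated T cells also express: the costimulatory receptor Tnfrsf4 (383 ± 180 TPM), the interleukin 2 receptor chain Il2ra (162 ± 67.9 TPM), Tnfrsf18 (139 ± 55.7 TPM; 27.2% of its exonic length under exons of Gm16008) and Ctla4 (115 ± 49.9 TPM). Ikzf2, Ikzf4, Gpr83, Itgae, Lrrc32 and Entpd1 were each below 2.3 TPM on average. In the Tfh list, Cd200 stood at 161 ± 69.8 TPM, Pdcd1 at 75.9 ± 34.7 TPM and Btla at 75.3 ± 28.0 TPM, and Bcl6, Cxcr5 and Il21 were below 2 TPM.

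Tbx21 was above Gata3 by a log2 ratio of 3.62 in replicate 1 and 3.46 in replicate 3. In replicate 2, where Gata3 had 0 counts, it was at least 3.20-fold higher if its own 6 counts are taken as exact. Against Bcl6 it was 56.2-fold above in replicate 1 and 62.4-fold in replicate 3. Against Foxp3 the log2 ratio was 0.47 in replicate 1 (exact 95% counting interval 0.29 to 0.64), 0.46 in replicate 2 (-1.39 to 2.26) and -0.84 in replicate 3 (-1.06 to -0.64), so its sign differed between libraries by more than counting error. Foxp3 (chromosome X, 7579676 to 7595243, plus strand) has 14.8% of its exonic length under exons of Ccdc22, a gene chosen after its values were seen that had 4, 0 and 8 counts. Counting on the opposite strand would itself leave Ccdc22 low, so its counts do not show that it was silent. The log2 CPM ratio of replicate 3 to replicate 1 was 0.70 for Foxp3 and -0.61 for Tbx21. Class medians were 0.78 for embedded genes and -0.84 without overlap, and overlaps of up to 50% had quartiles of -0.78 and 0.72. Whether the change of sign came from this split was not tested. An exact two-sided sign-flip test over 3 libraries cannot go below p = 0.25, nor below 0.50 over the 2 libraries with counts for Gata3 and Bcl6.

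Il2, the T-cell growth factor, was the highest interleukin gene at 861, 830 and 352 TPM in replicates 1, 2 and 3 (chromosome 3, 37120523 to 37125959, minus strand). Ifng was below it in 3 of 3 libraries, with a log2 ratio of -4.02 ± 0.32 (n = 3; exact sign-flip p = 0.25, the smallest possible). Ifng was 5.68-fold above Il4 in replicate 1 and 1.74-fold in replicate 3; with 2 counts of each gene, replicate 2 gave a log2 ratio of -0.08 (exact interval -3.86 to 3.71). The mean log2 ratio to Il4 was 1.08 ± 1.31 (n = 3; exact sign-flip p = 0.50), 1.65 without replicate 2 and 0.36 without replicate 1. It was 4.11-fold above Il13 in replicate 1 and 2.41-fold in replicate 3. Il17a had no count, so Ifng was at least 45.2-fold higher in replicate 1 and at least 13.3-fold higher in replicate 3. Il10 had 1, 1 and 0 counts. The log2 ratio of Ifng to it was 7.25 in replicate 1 (exact interval 4.75 to 12.56), and Ifng was at least 14.8-fold higher in replicate 3. In replicate 2, with 2 counts of Ifng, the ratio was 1.02 (-3.25 to 6.90), which does not show Ifng above Il10. Of the other cytokines, Tnf stood at 147 TPM, the colony-stimulating gene Il3 at 125 TPM and Ltb at 53.8 TPM on average, and Csf2 at 160, 0 and 52.0 TPM in replicates 1, 2 and 3; 12% of the exonic length of Csf2 lies under exons of Gm12223. Ccl3 (363, 216 and 148 TPM) and Ccl4 (191, 688 and 81.5 TPM) led the chemokines; Ccl4 was above Ccl3 only in replicate 2, with 11 counts. The next by mean TPM, Cxcl2, rested on 2 counts.

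**Figure D2:**
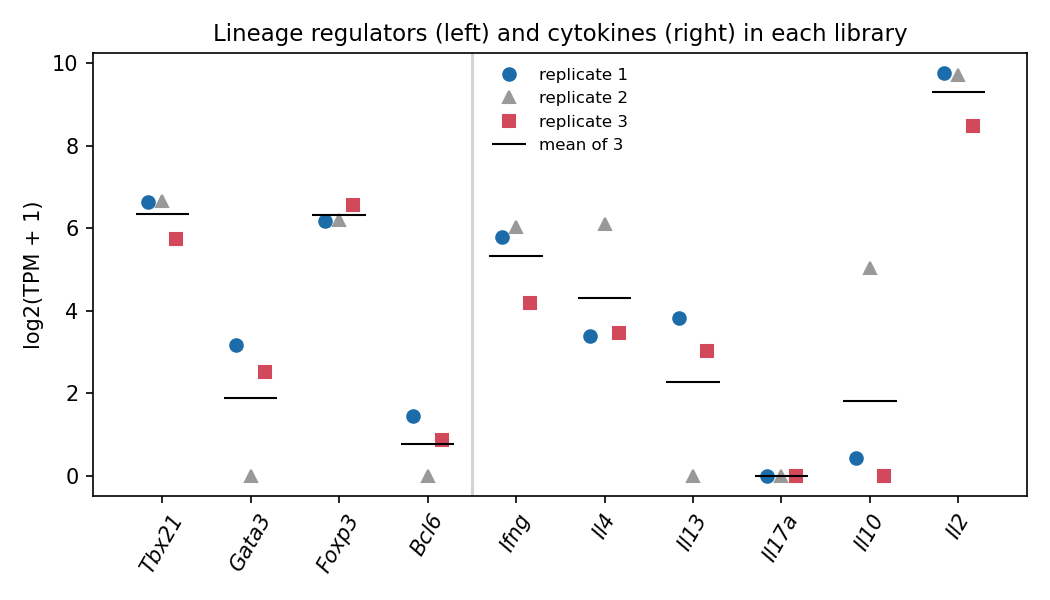
Levels as log2(TPM + 1) (y axis) of 4 lineage regulators and 6 cytokines (x axis) in replicates 1 (circles), 2 (triangles) and 3 (squares), with the mean of the 3 as a line. Tbx21 lies above Gata3 and Bcl6 in each library, Foxp3 lies above it in replicate 3, and Il2 lies above Ifng in each library; replicate 2 rests on 50627 counts.

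Cell cycle genes were expressed throughout. All 12 genes of the S phase list and all 14 of the mitosis list reached 1 TPM in every library, with medians of 6.50 ± 0.53 and 5.72 ± 0.61. Pcna, the replication clamp, stood at 190 ± 81.3 TPM, Rrm2 at 163 ± 70.7 TPM, Top2a at 140 ± 55.2 TPM and Mki67 at 136 ± 47.6 TPM. The glycolysis list had a median of 7.22 ± 0.46, led by Ldha (844 ± 386 TPM), Tpi1 (520 ± 247 TPM), Gapdh (811, 290 and 312 TPM in replicates 1, 2 and 3) and Pkm (457 ± 183 TPM). Stress genes had a median of 5.78 ± 0.88, with the chaperone Hsp90b1 at 475 ± 170 TPM and Atf4 at 416 ± 157 TPM; 10.3% of the exonic length of Hsp90b1 lies under exons of 1810014B01Rik.

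Genes induced by interferon gamma stood higher than those of the type I interferon list. In the first, 10 of 12 members reached 1 TPM in every library, 11 did in both replicates 1 and 3, and the median was 5.11 ± 0.62, with Igtp at 208 ± 83.0 TPM, Gbp2 at 169 ± 66.1 TPM and Psmb8 at 108 ± 63.0 TPM. In the second, 2 of 12 did so in every library and 5 in both replicates 1 and 3, and the median was 0.19 ± 0.17; Bst2 (106 ± 43.8 TPM) and Stat2 (8.12, 20.9 and 4.19 TPM, with 3 counts in replicate 2) were the 2. The difference between these 2 lists was not tested. Of immediate early genes, Junb (357 ± 85.3 TPM), Jund, Ier2 and Dusp2 were highest, and 10 of 16 reached 1 TPM in every library and 15 in both replicates 1 and 3; 52.6% of the exonic length of Jund lies under exons of Gm11175. Of the naive T cell list, 9 of 12 reached 1 TPM in every library and 10 in both replicates 1 and 3, with Ccr7 (127 ± 75.3 TPM) and Tcf7 (112 ± 44.9 TPM) highest. Of the inhibitory receptor list, 7 of 12 did in every library and 9 in both replicates 1 and 3, led by Ctla4, Pdcd1 and Btla. Lag3 (44.5, 157 and 12.7 TPM) ranked next by mean TPM because of 8 counts in replicate 2.

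Markers of other cells were few, though Ighm, Cd74 and Csf1r each had a higher mean TPM than Ifng (45.0 TPM). The medians of the cytotoxic, myeloid, granulocyte, natural killer, erythroid and platelet, and stromal and epithelial lists were 0 in all 3 libraries. The natural killer list had 1 count in all and the granulocyte list 2, 1 and 11. Of the cytotoxic list, Cd8b1 (21, 1 and 13 counts) and Crtam (38, 1 and 13 counts) were highest. Of the B cell list, Ighm, the immunoglobulin mu constant region, had 404, 1 and 172 counts (56.1 ± 40.0 TPM). Cd79a had 10, 0 and 22 counts. Of the myeloid list, Cd74 stood at 61.1 ± 29.0 TPM and Csf1r at 119 ± 42.9 TPM; 17.8% of the exonic length of Csf1r lies under exons of Hmgxb3. Alas2 (3.34 ± 3.10 TPM) led the erythroid and platelet list, with 15.5% under exons of Apex2, and Pecam1 (5.92, 19.9 and 3.75 TPM) led the stromal and epithelial list.

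Mitochondrial genes took 1.15% of the counts of replicate 1 (exact 95% interval 1.14 to 1.16), 1.75% of replicate 2 (1.64 to 1.87) and 1.34% of replicate 3 (1.33 to 1.35), a mean of 1.41 ± 0.31%. As shares of TPM the mean was 4.85%. Within them mt-Nd6, the protein-coding gene of the minus strand, stood at 23098 ± 9724 TPM, against 2546 ± 1219 for mt-Nd5 and 2337 ± 954 for mt-Co1. If fragments were counted on the opposite strand, as weighed below, the counts of mt-Nd6 would come from plus-strand fragments. Those of mt-Nd5 and mt-Co1, on the plus strand, would come from minus-strand fragments. The order of these genes and the mitochondrial share are therefore not read as their own expression. Of the 13 mitochondrial protein-coding genes, 5 had no count in any library. These lie in a single stretch of the mitochondrial genome, positions 7013 to 10173. The other protein-coding gene there, mt-Nd3, chosen after its values were seen, had 1, 0 and 4 counts. Whether reads were lost in this stretch was not tested, so these genes are not described as unexpressed. Ribosomal protein genes took 5.07%, 4.34% and 2.98% of counts in replicates 1, 2 and 3. The 10 highest genes took 5.55%, 6.97% and 9.51%. A list of 13 RNAs made without a poly(A) tail took 0.0397%, 0.0593% and 0.0229%, nearly all in mt-Rnr1 and mt-Rnr2. That list leaves out a gene annotated as ribosomal RNA, named here after its values were seen: CT010467.1 (chromosome 17, 39846353 to 39848827, minus strand), with 73.9% of its exonic length under exons of Gm42418, took 22230, 426 and 103032 counts, or 0.469%, 0.841% and 2.91%. Replication-dependent histone genes had 88, 0 and 69 counts, or 0.00186% of replicate 1 and 0.00195% of replicate 3. As shares of TPM instead of counts, the means over the 3 libraries were 5.75% against 4.13% for ribosomal protein genes, 11.2% against 7.34% for the 10 highest genes, 0.0695% against 0.0406% for the 13 RNAs without a poly(A) tail and 0.00397% against 0.00127% for histone genes.

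Sex-linked genes differed between libraries. Xist, the X-inactivation transcript (chromosome X, 103460375 to 103483217, minus strand), stood at 146 CPM in replicate 1 (exact 95% interval 135 to 157), 356 CPM in replicate 2 (211 to 562) and 0.847 CPM in replicate 3 (0.175 to 2.47). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d summed to 452, 1 and 261 counts, or 95.3 CPM (86.7 to 105), 19.8 CPM (0.50 to 110) and 73.6 CPM (65.0 to 83.1). Relative to the counts of genes without opposite-strand exons, the Y-linked sum of replicate 1 was 0.758 times that of replicate 3 (exact 95% interval 0.649 to 0.886). Of Xist, 11.3% of the exonic length lies under exons of Tsix, which had 789, 59 and 6 counts.

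Some lists stood apart in a library. Among 10000 random lists of matched expression, the median deviation of replicate 1 from the other libraries lay at percentile 98.4 for the T cell list (0.40 in log2 CPM), 98.8 for S phase (0.41), 99.4 for mitosis (0.49) and 99.98 for glycolysis (0.54). The mitochondrial list lay at percentile 99.8 in replicate 2 (0.19) and 0.32 in replicate 3 (-0.24). Its random lists, matched on expression but not on overlap, had medians of -0.25 in replicate 2 and 0.95 in replicate 3. These 2 percentiles therefore also reflect shifts of the random lists. So does that of glycolysis in replicate 1, whose random lists had a median of -0.17. For the T cell, S phase and mitosis lists in replicate 1 that median was 0.04 to 0.08. In all, 6 of 39 list and library pairs lay outside the central 95%. Within genes without opposite-strand exons 1 of 33 was outside, glycolysis in replicate 1 at percentile 97.7 (0.31). Mitosis (0.32, percentile 95.4) and S phase (0.27, percentile 94.1) in replicate 1 stayed inside. The mitochondrial and naive T cell lists had fewer than 5 such genes and were not run, so the deviations of the mitochondrial list were not retested.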

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

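Settings limited to genes without opposite-strand exons, those naming replicates 1 and 3, and the correlations without each replicate were chosen after the counts were seen. Of 148 alternatives to 23 results, 119 kept the direction and side of the threshold, or, without a test, stayed within the spread (counts within 1.5 times); gene pairs were judged on direction alone, since no test over 3 libraries can pass. Some of the 119 could not have changed, so this number overstates stability. FPKM ratios of the 9 gene pairs equal their TPM ratios by construction. Leaving out replicate 2 could not move Tbx21 against Gata3 or Bcl6, or Ifng against Il13, where it gave no ratio. Leaving out replicate 1 kept the lowest correlation, which was that of replicates 2 and 3. Replicate 2, with 50627 counts, could not show genes below about 59.3 CPM. Posterior mean TPM was not run, since the files hold counts. No paired analysis was possible because there is 1 group.

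The number of expressed genes, 7469, was 14734 with the floor met in at least 1 library, 7498 to 12243 when each replicate was left out, and 4223 without opposite-strand genes, a smaller set by construction. The lowest correlation, 0.74, was 0.85 over all genes and 0.74 to 0.91 when a replicate was left out. The coefficient of variation, 0.341, was 0.241 to 0.365 leaving out replicates, 0.502 as DESeq2's median dispersion, 0.164 in genes without opposite-strand exons and 0.181 in those genes for replicates 1 and 3. Varying genes, 4681, numbered 271 to 4167 leaving out replicates, 560 without opposite-strand exons and 770 in those genes for replicates 1 and 3. List deviations outside the central range, 6, numbered 14 with no filter, over more lists, and 1 without opposite-strand exons, over fewer lists (not the mitochondrial list). The mitochondrial share, 1.41%, was 4.85% as TPM; leaving out replicates gave 1.24% to 1.55%.

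The Th1 against Th17 difference passed the threshold with a pseudocount of 0.1 (5.57, adjusted permutation p = 0.039), with list means (2.25, 0.040) and without replicate 2 (leaving out replicates gave 3.10 to 3.32); among members without opposite-strand exons it was 1.94 (0.74). In that setting the Th2 difference, 2.40, was 1.37 and the Treg difference, -0.56, was -1.80. These shifts depended in part on replicate 2: the same members with replicates 1 and 3 alone gave 2.90 for Th17, 2.36 for Th2 and -0.61 for Treg. All members with replicates 1 and 3 gave 3.32, 2.72 and -0.10, so limiting the members still lowered each difference. Leaving out replicates gave Treg differences of -0.76 to -0.10, the latter without replicate 2, and the difference was 0.14 among members at 1 TPM or more. The Tfh difference was 1.26 over all members without replicate 2. Among members without opposite-strand exons it was -1.18, and -0.14 with replicates 1 and 3 alone. Tbx21 against Foxp3, 0.03 on the log2 scale, was -0.65 from counts not divided by length and -0.19 without replicate 1 or without replicate 2 (highest 0.46, without replicate 3). Leaving out replicates gave log2 ratios of 0.36 to 1.65 for Ifng against Il4 and 1.02 to 7.25 for Ifng against Il10, whose counts were 0 or 1. Except where the members or libraries were fewer, the cause was not tested.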

Other observations

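The tests on sex-linked genes and on depth were chosen after the result was seen; those on strand, in all libraries and between replicates 1 and 3, were written before the values they measure were computed, though after antisense genes were seen among the highest counts. The bound of 60% for a clear majority of pairs was set after the shares were seen.

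Genes embedded in exons of an opposite-strand gene carried the higher counts. Unstranded reads or genomic DNA would give both strands alike counts and a median log2 ratio near 0, but the lower end of its interval was 3.26 in replicate 1. Correct strand assignment with antisense transcription would leave the host denser in most pairs, but the embedded gene was denser in 76.6% of pairs in replicate 3. Counting on the opposite strand of a stranded library is the only explanation weighed that these values do not argue against. The lower of the medians in replicates 1 and 3 was 3.82. It stays a candidate explanation, not a settled cause. Levels of genes such as Foxp3, Il12rb2, Ptgdr2, Csf1r and Gm20721 may therefore reflect transcripts of their overlap partners. On this explanation the doubt is not confined to overlap genes: levels of genes without overlap, such as Tbx21, Ifng, Il2 and Trac, would rest on the minor share of fragments assigned to the wrong strand. At the median pair the count per kb of the host was 7.09%, 3.21% and 2.62% of that of the embedded gene in replicates 1, 2 and 3. The alignments that would settle it were not used here, and no biological explanation was tested.

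Replicates 1 and 3 differed beyond counting error in 4167 of 11003 genes. The lower depth of replicate 3 as the whole cause is argued against. With replicate 1 thinned at random to the total of replicate 3, 37.2% of genes varied, against 37.9% before. Values were also scaled to library totals, so depth would move embedded and no-overlap genes alike. Their medians differed by 1.62 on the log2 scale with quartiles that did not meet, a split already known when this prediction was written. A different share of reads counted from the annotated strand is a candidate explanation, as it would part these classes by such a difference (1.62), and the coefficient of variation of these libraries was 0.181 in genes without opposite-strand exons against 0.363 over all. This may also underlie list deviations: with replicate 3 set against replicate 1 alone, settings chosen after the counts were seen, the T cell, S phase, mitosis and glycolysis lists lay outside the central 95% over all genes (median log2 differences of -0.47 to -0.49), and none of the 11 lists did in genes without opposite-strand exons, S phase coming closest at percentile 3.23 (-0.14). The glycolysis deviation of replicate 1 that was left in those genes was measured against both other libraries and was not seen against replicate 3 alone (-0.11, percentile 8.59). No biological explanation was tested, since the libraries form 1 group.

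Xist and Y-linked genes were both counted in replicate 1. Cells of 1 sex would lack Xist or the Y-linked genes, but the lower end of the interval of Xist was 135 CPM beside 452 Y-linked counts, and Tsix, which would be counted in its place on the opposite strand, had 789 counts. Whether the Xist counts came from opposite-strand reads stays open: Xist and Tsix fell together from replicate 1 to replicate 3, with log2 ratios differing by -0.70, and so they would whichever strand the reads came from. A lower share of male RNA in replicate 1 than in replicate 3 is a candidate explanation only when set against genes without opposite-strand exons. Relative to all counts the Y-linked genes were higher in replicate 1, and the median log2 ratio of replicate 3 to replicate 1 over the 4 genes was -0.15, but it lay at percentile 99.3 of 10000 random sets of matched genes without opposite-strand exons, whose median was -0.85. Whether cells of both sexes were pooled or RNA was carried over between libraries was not tested.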
